A study of Mus musculus with 23 samples.

How the data were processed

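The series compared wild-type (WT) and Bach1-knockout mouse embryonic stem cells by polyA RNA sequencing and by chromatin immunoprecipitation (ChIP) sequencing of NANOG, H3K4me1, H3K4me3 and H3K27ac, and mapped FLAG-tagged BACH1 in cells carrying a doxycycline-inducible transgene, treated for 6 hours with 0.5 μg/μL doxycycline per the labels. Groups came from the sample titles, with 3 RNA libraries per genotype. The NANOG samples gave 2 lists per genotype, where replicate 1 pools 2 sequencing runs per the labels, and the other ChIP groups had 1 sample each. The name of the knockout NANOG list of replicate 1 carries 1 run number that the descriptions of its samples do not give, and those of both H3K4me1 lists carry 2 run numbers for 1 described sample, so which runs were pooled there is uncertain. No values of the 4 input samples were used here.

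Per the submitters' processing notes, reads were trimmed with Trim Galore, and mm9 is the build named for all samples. The notes name Bowtie2, MACS2, STAR, StringTie 1.3.4d and limma for the ChIP samples and HISAT2, HOMER and limma for the RNA samples, without saying which step each did, and give no counting or strand setting. The deposited RNA table gives TPM for 25124 genes, 1 RefSeq transcript each, with gene symbol, chromosome and cytogenetic band. TPM are scaled to the library and keep no read depth, and the listed ones sum to 604964 to 606200 per library, so part of each library lies outside the table. The authors' deposited lists of knockout-higher and knockout-lower transcripts give a log2 fold change and a p-value, with neither the scale's pseudocount nor any adjustment stated. The deposited NANOG and H3K4me1 lists have the narrow and broad peak layouts of MACS2 with a score, a fold enrichment ratio at the summit or over the region and −log10 p and q values. The deposited H3K4me3, H3K27ac and single-caller FLAG-BACH1 lists have the older MACS layout whose score is 10 times −log10 p, divided by 10 here to give −log10 p. The merged FLAG-BACH1 list deposited by the authors holds positions only as used here, and what was merged is not given in the sources used here. Peaks were called per list, with no read depth stated, so comparisons of peak numbers assume comparable depth. Scores are the authors' and ranked or filtered peaks within a list only.

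From the TPM, log2(TPM + 1) was computed, genes with at least 1 TPM in at least 3 of the 6 libraries were kept (12196), and knockout was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with Benjamini-Hochberg adjustment and calls at 0.05 without a fold threshold. 19 gene lists were fixed before the data were examined: naive pluripotency, shared pluripotency, formative and primed epiblast, primitive streak and mesendoderm, endoderm, neuroectoderm, trophectoderm, 2-cell-like, germ line, BACH1 and NRF2 targets, MLL and SET1 complexes, Nodal, WNT, glycolysis, cell cycle, p53 targets, fibroblast, mitochondrially encoded, and immediate early and stress. The 17 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Fry, a self-contained test from limma, and camera with an estimated correlation were alternatives. A further 6 lists were written after the results were seen and are used in the closing section only, tested on their members outside the earlier lists and largest changes, with p-values given before adjustment and, for the imprinted lists, also after adjustment over these 6. The level of 1 member of these lists is not reported here. The model recovered 44.0, 86.0, 98.0 and 100% of 50 genes each with simulated log2 changes of 0.25, 0.5, 1 and 2 among 12196 simulated genes, with 8 false calls of 172.

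Named genes followed a rule fixed in advance: Bach1, then the 10 largest rises and the 10 largest falls among called genes whose 3 knockout values all lay on one side of the 3 WT values, without predicted, unnamed and microRNA genes and genes with near-identical copies, then up to 4 members of each list with the smallest p, and Pou5f1, Sox2, Nanog, Klf4, Esrrb and Hmox1 in any case. Ly6a, Ly6c1, Obox6, Oas1a, Rhox6 and Rhox9 were left out of the largest changes as members of multigene families, a judgement made with their values at hand.

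Peaks were compared with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. An overlap was at least 1 bp. The share of WT peaks overlapping a knockout peak of the same mark and replicate was computed for WT peaks at FLAG-BACH1 peaks and for 10000 random sets of other WT peaks of the same number in each decile of signal, drawn without replacement. Signal was the fold enrichment for NANOG and H3K4me1 and the older MACS score for H3K4me3 and H3K27ac. The first version of the random sets drew with replacement, against the plan, and was corrected after its output had been seen. Shares of BACH1 peaks at WT marks were set against 1000 circular shifts along each chromosome, whose length was taken as the furthest peak end in any list. Intervals are 95% Wilson intervals. Coordinates are 1-based mm9. On 8000 simulated peaks, a planted difference of 0 points gave 1.14 points at percentile 85.0, and one of -15.0 points gave -16.5 points at percentile 0.

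The alternatives, fixed before the data were examined, were pseudocounts of 0.1 and 5, no filter on low values or a mean of at least 5 TPM, quantile normalization, median-of-ratios scaling, eBayes without trend or with robust estimation, the replicate number as a block, leaving out each library, a fold threshold, a stricter peak threshold (−log10 p of at least 10), a 50% overlap, lists of equal length, the merged BACH1 list and BACH1 peaks within 1 kb. Scaling without ribosomal proteins, genes with 1 curated RefSeq transcript and matching on width were added after the data were seen. The number of RefSeq transcripts per gene came from a name table of assembly GRCm38.p6, whose coordinates were not used. No mm9 annotation was used here, so peaks were not assigned to genes, and the planned comparisons of BACH1, NANOG and histone peaks at changed genes were not analysed here.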

Results

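The study examined what loss of BACH1, a heme-responsive transcription factor of the CNC family, does to gene expression, NANOG binding and histone marks in E14Tg2A mouse embryonic stem cells, a line grown here on gelatin with serum and leukemia inhibitory factor. The 23 samples held 6 polyA RNA libraries, 3 from wild-type (WT) cells and 3 from cells whose Bach1 gene had been targeted with CRISPR/Cas9 (knockout), 13 chromatin immunoprecipitation (ChIP) samples and 4 input samples, for which no values were used here. The ChIP samples gave 12 peak lists: NANOG in WT and knockout cells in replicates 1 and 2, H3K4me1, H3K4me3 and H3K27ac once per genotype, and 2 lists of FLAG-tagged BACH1 in cells induced with doxycycline for 6 hours. H3K4me3 marks promoters, H3K4me1 marks enhancers and H3K27ac marks active ones of both kinds. RNA values were TPM with 1 transcript per gene, which keep no read depth, so depth and counting error were unknown. The listed TPM summed to between 604964 and 606200 per library, and 11475 to 11695 genes reached 1 TPM. RNA values below are means ± SD with n = 3 per genotype, log2 fold changes are knockout minus WT on the log2(TPM + 1) scale, which understates the change of low genes, and p-values are limma's after Benjamini-Hochberg adjustment. They measure the spread between these libraries, which the study's design text calls biological triplicates. The sample titles name no knockout clone. Other differences between the WT and knockout cells therefore cannot be told apart from the loss of BACH1.

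Bach1 RNA was low in both genotypes and lower in the knockout. It stood at 2.35, 2.5 and 2.7 TPM in the WT libraries and at 1.69, 1.76 and 2.05 TPM in the knockout libraries, so each knockout library lay below each WT library. The mean went from 2.52 ± 0.177 to 1.83 ± 0.188 TPM, a log2 fold change of -0.31 (SE 0.0717, adjusted p = 0.00282). With median-of-ratios scaling between libraries the log2 fold change was -0.17 and no longer passed (adjusted p = 0.0545). Where in the gene the edit lies is not given in the sources used here, so the transcript level shows neither the presence nor the absence of a working protein.

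The RNA comparison asked which genes differed between the WT and knockout cells. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1 and is a classic target repressed by BACH1, rose 3.73-fold from 81.6 ± 2.02 to 304 ± 2.04 TPM (adjusted p = 5.00e-11). Of the core pluripotency regulators, Nanog fell from 306 ± 2.52 to 116 ± 4.73 TPM (adjusted p = 7.18e-10), Klf4 from 44.4 ± 1.24 to 10.6 ± 0.463 TPM (adjusted p = 6.30e-10), and Esrrb from 124 ± 2.04 to 68.8 ± 1.11 TPM (adjusted p = 4.40e-09). Sox2 fell less, from 142 ± 2.93 to 106 ± 1.84 TPM (adjusted p = 3.51e-07), and Pou5f1, which encodes OCT4, rose from 1232 ± 21.6 to 1557 ± 28.5 TPM (adjusted p = 3.51e-07). In each of these genes the 3 knockout libraries all lay on one side of the 3 WT libraries.

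**Figure D1:**
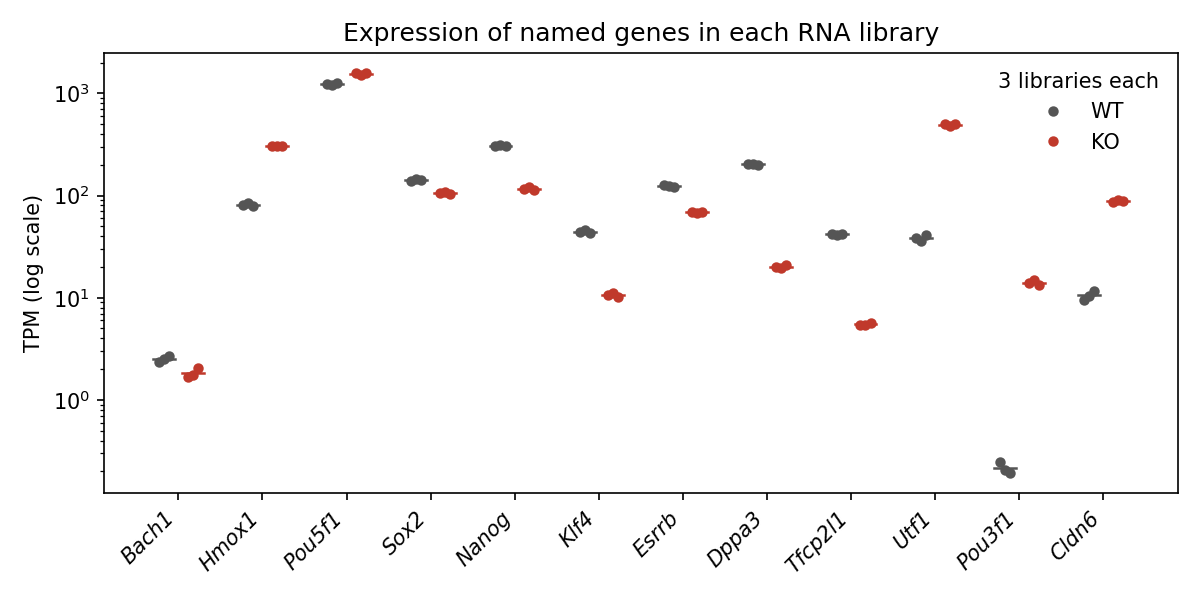
Expression of 12 named genes in each of the 6 RNA libraries, in TPM on a log axis, with a line at the mean of each genotype. Points are single libraries. Nanog, Klf4, Esrrb, Dppa3 and Tfcp2l1 lie lower and Hmox1, Utf1, Pou3f1 and Cldn6 lie higher in the knockout libraries.

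The largest rises were in genes of varied function. Dnmt3l, a cofactor of the de novo DNA methyltransferases, rose from 16.2 ± 0.801 to 461 ± 3.05 TPM (adjusted p = 6.38e-12), and H19, a maternally expressed imprinted noncoding RNA, rose from 14.5 ± 0.392 to 356 ± 3.67 TPM (adjusted p = 2.68e-12). Id1, an inhibitor of basic helix-loop-helix factors that responds to BMP signals, rose from 13.5 ± 1.09 to 222 ± 0.743 TPM (adjusted p = 4.76e-11). Dusp4 and Spry4, feedback inhibitors of ERK signalling, were near 0 in WT cells, at 0.322 ± 0.107 and 0.234 ± 0.0545 TPM, and reached 29.6 ± 1.10 and 21.6 ± 0.571 TPM. Col18a1, a basement membrane collagen, reached 103 ± 2.77 TPM, Krt17, a keratin, 51.3 ± 0.734, Car4, a membrane-bound carbonic anhydrase, 34.5 ± 0.744, Serpinf1, a secreted serpin, 32.8 ± 0.522, and Tmem54 18.0 ± 0.537. These 5 genes had log2 fold changes of 4.96, 4.36, 4.61, 4.08 and 4.15.

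The largest falls were in genes of varied function as well. Sp5, a transcription factor induced by WNT, fell from 58.3 ± 1.2 to 0.229 ± 0.133 TPM (adjusted p = 6.57e-11), and Cdx1, a homeobox gene with the same property, fell from 35.5 ± 1.09 to 0.375 ± 0.0390 TPM (adjusted p = 2.09e-11). Bhmt, which remethylates homocysteine with betaine, fell from 53.4 ± 0.207 to 0.196 ± 0.0251 TPM (adjusted p = 7.05e-12). Trpm1, a cation channel, fell from 66.7 ± 1.83 to 0.588 ± 0.0383 TPM, Aqp3, a channel for water and glycerol, from 224 ± 2.24 to 9.95 ± 0.613 TPM, and Crxos, a homeobox gene named for lying opposite Crx, from 285 ± 6.16 to 6.93 ± 0.511 TPM. Tnni1, a troponin of slow muscle, Aurkc, a meiotic Aurora kinase, Grin1, an NMDA receptor subunit, and Serpinb1a, a protease inhibitor, fell by 4.57, 4.26, 3.97 and 3.91 on the log2 scale. Whether reads were counted by strand is not given in the sources used here, so Crxos and Crx reads cannot be separated.

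Over all genes, 10127 of 12196 tested genes passed, 3446 higher and 6681 lower in the knockout, and 2080 of them changed at least 2-fold, 809 higher and 1271 lower. The lead of lower genes among these turned over with scaling, at 1032 higher and 928 lower after quantile normalization and 1062 and 924 after median-of-ratios scaling, and their number was 2970 with a pseudocount of 0.1 and 771 with one of 5. Replicate libraries correlated at 0.997 or more across genes (Pearson, log2 values), WT and knockout libraries at 0.915 to 0.916, and the median SD within a genotype was 0.0582 in WT and 0.0564 in knockout libraries on the log2 scale. The median log2 fold change of all tested genes was -0.20, and the split of calls moved with the scaling between libraries: 34.0% of calls were higher in the knockout as deposited, 47.6% after quantile normalization (4612 higher, 5087 lower, median -0.03) and 48.5% after median-of-ratios scaling (4737 higher, 5025 lower, median -0.02). Ribosomal protein genes took 29.7 ± 0.181% of the listed TPM in WT and 34.2 ± 0.153% in knockout libraries, and scaling on the other genes, a choice made after that was seen, gave 3985 higher and 5963 lower.

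The genes that moved between pluripotent states were tested as lists fixed before the data were examined. Of 20 tested naive pluripotency genes, 14 fell and 4 rose. Dppa3, a maternal factor that protects DNA methylation, fell from 202 ± 2.85 to 20.1 ± 0.554 TPM, Tfcp2l1, a naive transcription factor, from 41.9 ± 0.454 to 5.5 ± 0.179 TPM, and Socs3, a feedback inhibitor induced by LIF through STAT3, from 68.1 ± 1.34 to 14.1 ± 0.844 TPM. The list fell by camera, limma's competitive set test (adjusted p = 0.0419, or adjusted p = 0.128 with an estimated correlation). That call also ended with the replicate number as a block (adjusted p = 0.0526), without the variance trend (adjusted p = 0.0591) and among genes with 1 curated transcript (adjusted p = 0.192). Of 17 tested genes of the formative and primed epiblast, 15 rose and 2 fell. Pou3f1, the POU factor OCT6, went from 0.215 ± 0.0276 to 14 ± 0.759 TPM, Dusp6, an ERK phosphatase, from 0.646 ± 0.0894 to 18.6 ± 0.390 TPM, Cldn6, a claudin of tight junctions, from 10.6 ± 1.07 to 88.3 ± 1.65 TPM, and Pim2, a serine/threonine kinase, from 8.28 ± 0.350 to 59.2 ± 2.00 TPM. This list rose (adjusted p = 1.13e-07, or adjusted p = 0.0672 with an estimated correlation). Of 20 genes listed as shared by pluripotent states, 16 rose and 4, Sox2 among them, fell (adjusted p = 8.76e-06, or adjusted p = 0.121 with an estimated correlation). That list holds Otx2, also a factor of the formative and primed state, which rose from 3.27 ± 0.302 to 22.3 ± 1.01 TPM. Its rise is thus not wholly separate from that of the formative and primed list. Utf1, a chromatin factor of pluripotent cells, rose from 38.6 ± 2.36 to 491 ± 9.11 TPM, Phc1, a Polycomb subunit, from 37.9 ± 1.42 to 181 ± 0.957 TPM, Jarid2, a partner of Polycomb complex PRC2, from 22.4 ± 0.518 to 68.6 ± 1.23 TPM, and Dppa4, a pluripotency-associated chromatin protein, from 41.0 ± 0.945 to 109 ± 0.347 TPM.

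**Figure D2:**
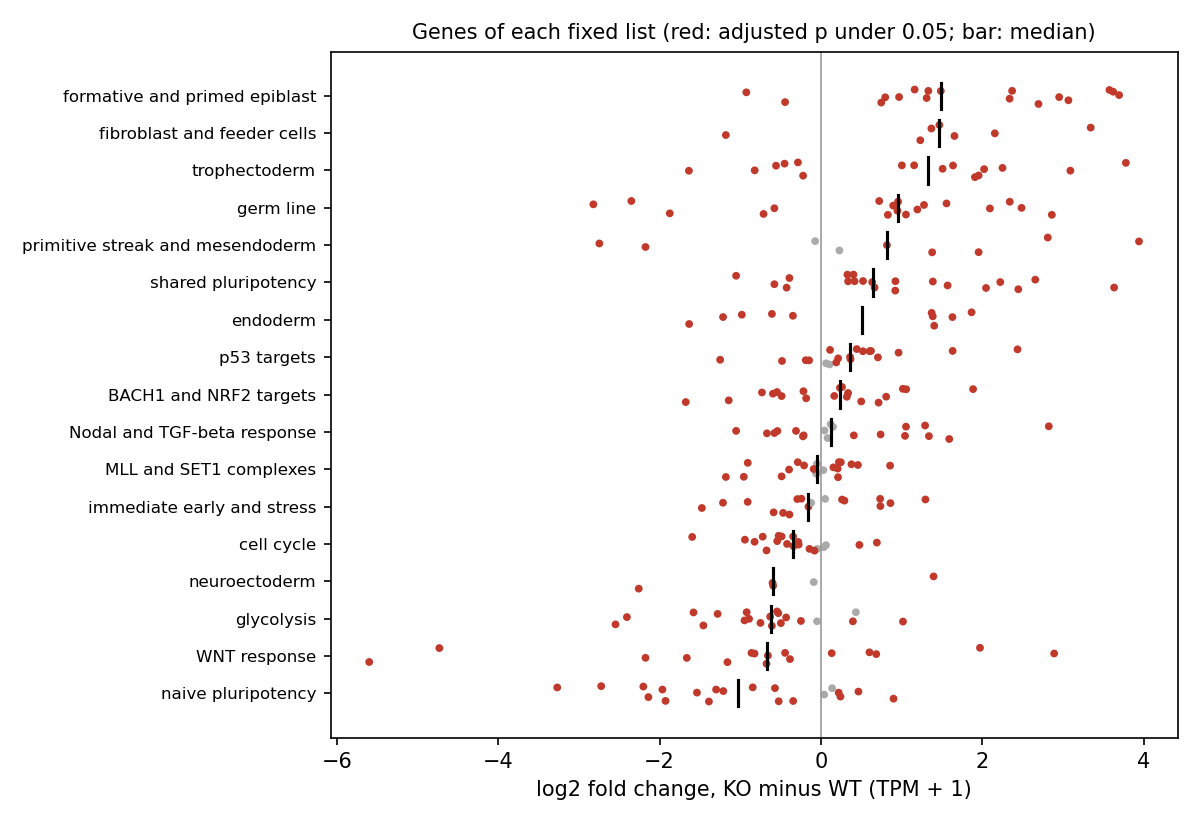
Log2 fold change (knockout minus WT, TPM + 1) of each tested gene in the 17 lists with enough tested members. Red points passed at an adjusted p under 0.05, grey points did not, and the black bar is the list's median, which ran from 1.49 in the formative and primed list to -1.03 in the naive list.

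Markers of other lineages moved in both directions. Of 16 trophectoderm genes, 10 rose and 6 fell (adjusted p = 0.00344, or adjusted p = 0.128 with an estimated correlation), with rises of the epithelial keratins Krt18, from 14.4 ± 1.17 to 211 ± 4.18 TPM, and Krt8, from 47.8 ± 0.717 to 151 ± 1.11 TPM, of the galectin Lgals3, from 8.29 ± 0.877 to 78.0 ± 0.772 TPM, and of the imprinted placental gene Peg10, from 9.06 ± 0.844 to 46.8 ± 1.35 TPM. Of 9 primitive streak and mesendoderm genes, 5 rose and 2 fell (adjusted p = 0.0328, or adjusted p = 0.128 with an estimated correlation), and that call ended after quantile normalization (adjusted p = 0.102), median-of-ratios scaling (adjusted p = 0.111) and scaling without ribosomal proteins (adjusted p = 0.0571). The list also lost its call among genes with 1 curated transcript (adjusted p = 0.738). Its members parted: Id1 and the growth factor Fgf17 rose, the latter from 3.32 ± 0.149 to 29.3 ± 1.67 TPM, whereas the streak transcription factors T (Brachyury) and Gsc fell from 4.60 ± 0.397 to 0.240 ± 0.0608 TPM and from 8.56 ± 0.326 to 0.433 ± 0.189 TPM. Of 10 endoderm genes, 5 rose and 5 fell (adjusted p = 0.321). Laminin Lamb1 rose by 1.87 on the log2 scale and the endocytic receptor Lrp2 by 1.63, laminin Lama1 fell by 1.63 and the matrix protein Sparc fell by 1.21. Of 5 neuroectoderm genes, 1, the retinoic acid binding protein Crabp2, rose from 1.24 ± 0.423 to 4.86 ± 0.675 TPM and 3 fell (adjusted p = 0.508): the RNA-binding protein Msi1 fell by 2.26, the neuronal tubulin Tubb3 by 0.60 and nestin, Nes, by 0.59.

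Germ line genes rose in 13 cases of 18 and fell in 5 (adjusted p = 0.00170, or adjusted p = 0.121 with an estimated correlation), and the call ended when only genes with a mean of at least 5 TPM were tested (adjusted p = 0.153). Mael, of the piRNA pathway, rose from 1.24 ± 0.0776 to 8.57 ± 0.237 TPM, the X-linked homeobox gene Rhox5 from 30.7 ± 1.19 to 75.9 ± 2.25 TPM and its relative Rhox6 from 8.27 ± 0.883 to 66.2 ± 0.283 TPM, while Stra8, a gatekeeper of meiosis, fell from 16.7 ± 0.868 to 1.52 ± 0.246 TPM. The 3 tested genes of the 2-cell-like state, Tcstv3, Zscan4c and Gm5662, rose to 2.09 ± 0.295, 1.72 ± 0.224 and 1.81 ± 0.265 TPM from below 1 TPM and were too few for a set test. Markers of fibroblasts, the cells of feeder layers, also rose in 6 of the 7 cases tested (adjusted p = 0.00173, or adjusted p = 0.128 with an estimated correlation). Tagln, an actin-binding protein, went from 1.83 ± 0.277 to 27.7 ± 1.12 TPM, the matrix metalloproteinase Mmp2 from 1.31 ± 0.0931 to 9.31 ± 0.379 TPM, the surface protein Thy1 from 3.11 ± 0.192 to 12 ± 0.501 TPM and Loxl1, a lysyl oxidase, from 0.495 ± 0.107 to 2.86 ± 0.188 TPM. The other 13 of the 20 markers, the collagen genes Col1a1, Col1a2 and Col3a1 among them, stayed below the filter on low values. Rhox6, Zscan4c, Tcstv3 and Gm5662 belong to families of near-identical copies, and Nanog, Pou5f1, Tpi1 and Fth1 have pseudogenes, so their values are uncertain where reads were shared.

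Genes with the DNA elements that BACH1 and its competitor NRF2 both bind moved in both directions: 11 of 19 rose and 8 fell (adjusted p = 0.0644). Besides Hmox1, the ferritin heavy chain Fth1 rose from 679 ± 5.75 to 1415 ± 15.9 TPM (adjusted p = 1.26e-10). Me1, the cytosolic malic enzyme, fell from 19.3 ± 0.294 to 5.37 ± 0.218 TPM (adjusted p = 2.32e-09), and Gsr, glutathione reductase, fell from 40.2 ± 0.463 to 17.7 ± 0.743 TPM (adjusted p = 7.67e-09). Subunits of the MLL and SET1 histone H3 lysine 4 methyltransferase complexes did not pass as a group, with 8 of 20 rising and 8 falling (adjusted p = 0.625), a split of 11 and 6 after quantile normalization and of 13 and 5 after median-of-ratios scaling. Their median log2 fold change was -0.05 and their mean -0.09, camera's direction was up and that of fry, a self-contained set test, was down, and the median was 0.16 after quantile normalization and after median-of-ratios scaling. Wdr5, a subunit of all these complexes, fell from 95.9 ± 0.0764 to 49.0 ± 0.808 TPM (adjusted p = 2.04e-09), as did Ash2l, from 143 ± 1.72 to 102 ± 1.42 TPM, Paxip1, from 9.94 ± 0.112 to 4.84 ± 0.216 TPM, and Ncoa6, from 9.79 ± 0.272 to 3.78 ± 0.478 TPM.

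In signalling and metabolism, Nodal pathway genes stood out for Lefty1 and Lefty2, secreted Nodal antagonists, which rose from 12.3 ± 0.190 to 93.0 ± 0.499 and from 44.1 ± 0.676 to 135 ± 2.65 TPM. Nodal itself rose from 26.1 ± 1.87 to 65.4 ± 1.65 TPM and Gdf3, a related ligand, fell from 74.2 ± 2.37 to 35.3 ± 0.550 TPM. The list of 19 had 8 rises and 7 falls (adjusted p = 0.0262, or adjusted p = 0.128 with an estimated correlation), or 11 and 4 after quantile normalization and after median-of-ratios scaling, and its call ended with median-of-ratios scaling (adjusted p = 0.0595). It also ended among genes with 1 curated transcript (adjusted p = 0.192). Of 16 WNT response genes, 11 fell and 5 rose (adjusted p = 0.321). Cyclin D1, Ccnd1, fell from 49.6 ± 0.644 to 21.7 ± 0.298 TPM and Myc, a growth-promoting transcription factor, rose from 2.27 ± 0.394 to 23.2 ± 1.29 TPM. Of 20 glycolysis genes, 16 fell and 2 rose (adjusted p = 0.00386, or adjusted p = 0.121 with an estimated correlation): hexokinase Hk1 went from 49.7 ± 1.62 to 8.57 ± 0.318 TPM, the glucose transporter Slc2a3 from 367 ± 1.24 to 150 ± 1.17 TPM, triosephosphate isomerase Tpi1 from 413 ± 5.49 to 150 ± 2.84 TPM and Gpi1, glucose-6-phosphate isomerase, from 313 ± 0.266 to 168 ± 1.41 TPM.

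Of 20 cell cycle genes, 15 fell and 2 rose (adjusted p = 0.0693), a split of 12 and 5 after quantile normalization. The replication helicase subunits Mcm6 and Mcm4 fell by 0.82 and 0.94 on the log2 scale, the S phase regulator E2f1 fell by 1.59 and cyclin Ccnb1 fell by 0.67. The list passed when no filter on low values was applied (adjusted p = 0.00852). Of 19 p53 targets, 13 rose and 4 fell (adjusted p = 0.00173, or adjusted p = 0.128 with an estimated correlation). Perp, Bbc3 and Mdm2, a membrane effector, a death effector and the p53 ubiquitin ligase, rose by 2.44, 1.63 and 0.60, and Cdkn1a, the cell cycle inhibitor p21, fell from 73.9 ± 1.62 to 30.5 ± 0.546 TPM. Of 17 immediate early and stress genes, 6 rose and 9 fell (adjusted p = 0.741), or 7 and 6 after quantile normalization and after median-of-ratios scaling, with a median of -0.15 and a mean of -0.09 while camera's direction was up and fry's was down. Heat shock protein Hspb1 rose by 1.30 and the stress pseudokinase Trib3 by 0.74, the phosphatase Dusp1 fell by 1.21 and asparagine synthetase, Asns, fell by 0.91. None of the 13 mitochondrially encoded transcripts was tested.

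Together 10 of the 17 testable lists passed with the preset correlation of 0.01 and 0 passed with an estimated one. The estimate lay below the preset in the naive (-0.036), formative and primed (0.006), primitive streak (-0.077), germ line (-0.032), Nodal (-0.013) and glycolysis (-0.028) lists. A higher correlation is thus not what ended their calls. The estimate lay above the preset in the shared pluripotency (0.081), trophectoderm (0.030), p53 (0.086) and fibroblast (0.123) lists. Camera with an estimated correlation takes its p-values from the residual degrees of freedom of the 6 libraries. With the preset it takes them from the number of genes, which gives smaller p-values at an equal statistic. The 0 calls therefore cannot be put down to correlation between genes alone. At an unadjusted p under 0.05 the estimated correlation left the formative and primed, shared pluripotency, trophectoderm, germ line and glycolysis lists. The numbers of genes that rose and fell were the same in each list when adjusted over the list alone as when adjusted over all genes. In the other 9 splits of the 6 libraries camera also passed 4 to 7 lists. Each of those splits mixes the genotypes in unequal numbers, so part of the genotype difference stays in it. These counts are therefore no null for the list calls. Genes of chromosome 6, which carries Nanog, Dppa3, Gdf3, Slc2a3, Tpi1, Asns and Stra8, all lower in the knockout, and Phc1 and Peg10, both higher, had a median log2 fold change of -0.37 against -0.19 elsewhere.

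The authors' deposited lists held 1883 transcripts higher and 2523 lower in the knockout, with absolute log2 fold changes of at least 1 and p-values up to 0.0492 and 0.0499. Of these, 1177 and 1838 passed the filter on low values used here, and each of them was called in the same direction. They covered 788 of the 809 genes at least 2-fold higher and 1224 of the 1271 at least 2-fold lower. In the authors' deposited table, Nanog had a log2 fold change of -1.41, Klf4 -2.06 and Hmox1 1.91, computed from the same libraries and so not independent of the values above.

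The NANOG comparison asked whether NANOG binding differed between the WT and knockout cells, and its replicates pointed in opposite directions. In replicate 1, which pools 2 sequencing runs, and whose knockout list names a run other than one of those described for its samples, the number of NANOG peaks went from 9247 in WT to 2071 in the knockout, a log2 ratio of -2.16. In replicate 2 it went from 10031 to 20025, a log2 ratio of 1.00. Among peaks with a −log10 p of at least 10 the log2 ratios were -1.91 and 0.54. The mean log2 ratio of -0.58 ± 2.23 (SD, n = 2) was smaller than the spread between replicates, and an exact two-sided permutation test of 2 lists against 2 could not give a p below 0.33. The WT lists themselves shared little, with 15.6% of replicate 1 peaks overlapping a replicate 2 peak (95% Wilson interval 14.9 to 16.4). Of the 1444 WT replicate 1 peaks found in both, 36.6% overlapped a knockout peak of replicate 1, 42.6% one of replicate 2 and 39.3% neither.

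Each histone mark had 1 list per genotype, so their differences had no replicate check. H3K4me3 peaks went from 18779 covering 52.8 Mb in WT to 11157 covering 33.6 Mb in the knockout, and H3K27ac peaks from 44579 covering 36.9 Mb to 25755 covering 19.5 Mb. H3K4me1 peaks went the other way, from 36001 covering 65.6 Mb to 54227 covering 112 Mb. Of the WT peaks, 59.5% of H3K4me3, 46.1% of H3K27ac and 86.5% of H3K4me1 overlapped a knockout peak, while 99.6%, 82.3% and 52.6% of knockout peaks overlapped a WT one. The H3K4me1 lists each name 2 runs although 1 sample per genotype is described, so runs may have been pooled. Depths of the ChIP libraries were unknown, and peak numbers move with depth. H3K4me3 peaks of the weakest WT quartile by signal were kept in 3.43% of cases and those of the strongest in 99.8%.

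FLAG-BACH1 peaks in the induced cells met WT histone mark and NANOG peaks more often than shifted positions did. H3K4me1 without H3K4me3 was found at 38.0% of them, and H3K4me1 with H3K27ac and without H3K4me3 at 12.3%. Of 2132 BACH1 peaks on the main chromosomes, 50.4% overlapped a WT H3K4me1 peak (95% Wilson interval 48.3 to 52.5), 36.3% an H3K27ac peak (34.3 to 38.4) and 26.3% an H3K4me3 peak (24.4 to 28.2). These shares were 12.1, 11.3 and 8.67 times the mean of 1000 circular shifts of the BACH1 peaks along their chromosomes. NANOG peaks of replicate 1 met 20.5% of BACH1 peaks (18.9 to 22.3), 33.7 times the shifted mean, and those of replicate 2 met 10.2% (8.97 to 11.5), 18.6 times it, and 25% met a WT NANOG peak of either replicate. No shifted set reached an observed share. The shifts spread peaks over all parts of a chromosome, so these folds do not separate joint binding from a shared lean towards marked chromatin. The shares moved with the settings. NANOG of replicate 2 met 1.69% with at least 50% of the BACH1 peak covered and 4.08% with a −log10 p of at least 10. NANOG of replicate 1 met 12.5% with the merged list. H3K4me1 met 39.96% with the 50% overlap and 0% at the stricter threshold, which left 7 WT peaks. None of the histone marks met 32.3% of the BACH1 peaks, and of these 6.54% met NANOG. The intervals here and below cover counting error only.

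The strongest BACH1 peak by the authors' score lay on chromosome 8 from 87025100 to 87026450 (mm9; score 870.5), and overlapped H3K4me3, H3K4me1 and H3K27ac peaks in WT cells and an H3K4me1 peak alone in the knockout. The next, on chromosome 19 from 41529055 to 41530527 (score 849), overlapped NANOG of replicate 1, H3K4me1 and H3K27ac peaks in WT cells and H3K4me1 alone in the knockout. The third, on chromosome 3 from 122958783 to 122960332 (score 770.0), overlapped NANOG of replicate 1, H3K4me3 and H3K4me1 peaks in WT cells and H3K4me1 alone in the knockout. The knockout lists of H3K4me3, H3K27ac and NANOG of replicate 1 were shorter than the WT ones as a whole, and that of H3K4me1 was longer. These peaks therefore show no loss particular to BACH1 sites. No annotation of this build was used, so the genes at these peaks are not named.

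WT NANOG peaks at BACH1 sites were kept in the knockout more often than NANOG peaks of the same signal elsewhere, by an amount that depended on the settings. In replicate 1, 139 of 440 were kept, 31.6% (95% Wilson interval 27.4 to 36.1), against a mean of 25.8% in 10000 signal-matched random sets, at percentile 100. In replicate 2, 104 of 229 were kept, 45.4% (39.1 to 51.9), against 35.3%, at percentile 99.9. H3K4me1 went the same way, with 1016 of 1048 kept, 96.9% (95.7 to 97.8), against 88.2%, at percentile 100. The promoter and activity marks went the other way by a few points: 334 of 550 H3K4me3 peaks at BACH1 sites were kept, 60.7% (56.6 to 64.7), against 63.1%, at percentile 1.37, and 514 of 840 H3K27ac peaks, 61.2% (57.9 to 64.4), against 64.6%, at percentile 0.245. Without matching, every mark was kept more often at BACH1 sites than elsewhere, where the shares were 59.4% for H3K4me3 and 45.8% for H3K27ac. The deficits of these marks thus stand against signal-matched sets only. Their signal was the older MACS score, while that of NANOG and H3K4me1 was fold enrichment, so mark and matching measure cannot be told apart. With the merged BACH1 list the H3K4me3 difference was -0.59 points (percentile 9.73). Random sets matched on peak width as well, a choice made after BACH1 peaks were seen to lie in wide peaks, moved the H3K4me1 difference from 8.79 to 3.08 points and left NANOG of replicate 1 at percentile 93.3 and H3K4me3 at percentile 7.31. With at least 50% of the peak covered, NANOG of replicate 1 exceeded its matched sets by 2.08 points in place of 5.78 (percentile 91.5), and with a −log10 p of at least 10, replicate 2 by 5.94 points in place of 10.1 (percentile 90.7). With lists of equal length the excess of replicate 1 was 9.93 points (percentile 99.9). These percentiles describe the peak lists and are not p-values, since peaks are not replicates.

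**Figure D3:**
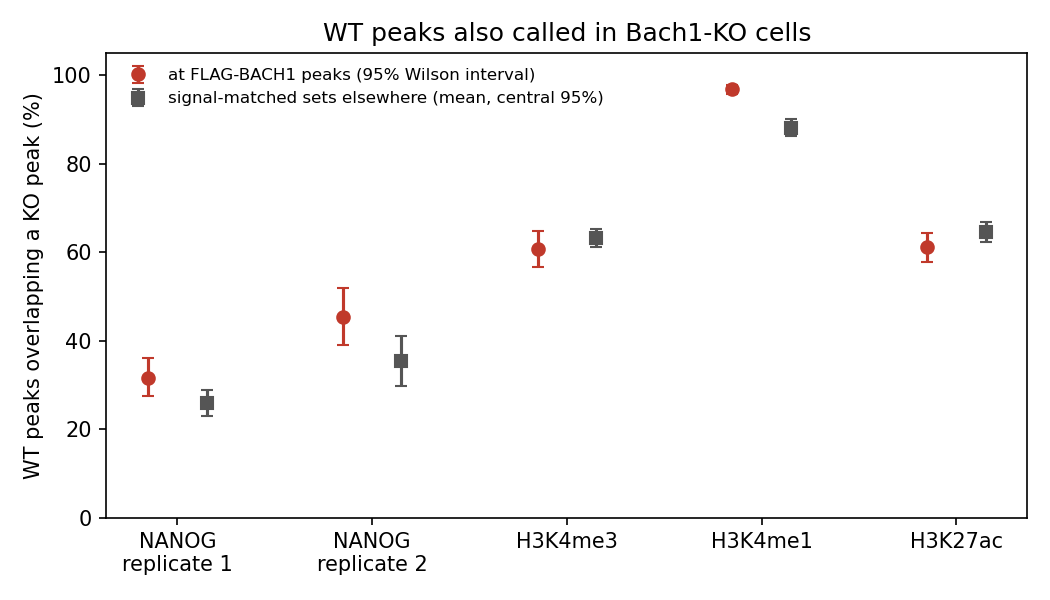
Share of WT peaks that overlap a knockout peak, in percent, for peaks at FLAG-BACH1 sites (red, with 95% Wilson intervals) and for signal-matched random sets of WT peaks elsewhere (grey, mean and central 95% of 10000 sets). The red points lie above the grey ones for both NANOG replicates and H3K4me1, and below them for H3K4me3 and H3K27ac.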

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

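Both tests of this pattern were chosen only after the result was seen. The merged FLAG-BACH1 list, which the comparisons above do not use as their main list, put 22.3% of its autosomal peaks on chromosome 11 and 11.6% on chromosome 8, against 11.3% and 7.43% in the single-caller list deposited under the same sample and 9.57% and 6.01% in WT H3K4me3 peaks, and was singled out as a signal in data outside the main measurement. What was merged is not given. Gene density cannot account for all of it, since chromosome 11 held 2.66 times the share of peaks found in the merged list alone that it held of WT H3K4me3 peaks. Extra copies of both chromosomes in the induced cells are a candidate that was not decided. The excess ran along both: 100% of the 10 Mb bins of chromosome 11 (11 of 11) and 11 of 12 bins of chromosome 8 held more such peaks than the median bin of other autosomes. Chromosomes picked for their excess tend to pass such a count, so it says little about copy number. The median bin held 125 such peaks on chromosome 11 and 66.5 on chromosome 8, against 18 on other autosomes. WT NANOG peaks of replicate 2 leaned the same way, with 12.3% on chromosome 11 and 9.78% on chromosome 8, so an uneven input or another mixture of cells stays open too.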

How the results depend on the processing

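Ribosome-free scaling, genes with 1 transcript and width matching were chosen only after the results were seen. The count of changed genes, 10127 (3446 higher, 6681 lower), fell to 6542 (2112, 4430) at a mean of at least 5 TPM and to 5228 (1798, 3430) with 1 curated transcript per gene, since fewer genes were tested, and to 2080 (809, 1271) with a 2-fold threshold, where the lead turned to higher genes with quantile normalization (1032, 928) and median-of-ratios scaling (1062, 924). Without one library it was 9806 to 9883 (3322 to 3371 higher, 6484 to 6532 lower), and 10 lists passed each time. The replicate number as a block gave 10149 (3457, 6692) and 9 lists; deviations of same-numbered libraries correlated at -0.003, 0.07 and -0.001, so the numbers do not pair the libraries. The block ended the naive pluripotency call (adjusted p = 0.0526), and not every library correlated best with its own number. Lists passing went from 10 to 0 with an estimated correlation and to 17 with fry, which tests the genes of a list without setting them against others. The naive pluripotency call also ended without the variance trend (adjusted p = 0.0591) and with 1 transcript (0.192), as did Nodal (0.192) and primitive streak (0.738) with 1 transcript. Of 301 alternatives of single lists 270 kept direction and side of the threshold, 20 lost a call, 6 gained one and 5 turned direction. With fry the MLL and SET1 list and the stress list passed downward where camera pointed up, with unadjusted p-values, signed by direction, of -0.000334 and -0.00178. The other turns passed neither way: MLL and SET1 at a mean of at least 5 TPM (-0.631) and, without a filter, stress (-0.916) and neuroectoderm (0.456). Of 1537 alternatives of named genes 1536 stayed, all but Bach1 with median-of-ratios scaling. Calls shared with quantile normalization kept their direction in 8489 of 8543 genes and with median-of-ratios scaling in 8471 of 8609.

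The NANOG log2 ratio of peak numbers, -0.58, was 1.00 without replicate 1 and -2.16 without replicate 2, and -0.69 with the stricter threshold, where replicate 2 alone gave 0.54. The mean excess of NANOG peaks kept at BACH1 sites, 7.93 points, was 10.1 and 5.78 without them. In replicate 1 the excess of 5.78 points was 2.08 with a 50% overlap, 2.39 matched on width, 9.93 with lists of equal length and 8.61 with the merged list, and in replicate 2 the excess of 10.1 was 5.94 with the stricter threshold and 4.12 with the merged list. The H3K4me1 excess of 8.79 points was 11.9 with a 50% overlap, 14.1 with lists of equal length and 3.08 matched on width. The H3K4me3 and H3K27ac deficits against matched sets ranged from -3.60 to -0.59 and from -5.11 to -2.35 points. BACH1 peaks at WT marks, with the merged list, a 50% overlap and the stricter threshold, met NANOG of replicate 1 in 12.5, 15 and 15.2%, NANOG of replicate 2 in 8.37, 1.69 and 4.08%, H3K4me1 in 35.2, 39.96 and 0%, and H3K27ac in 28.3, 25.5 and 29.2%. H3K4me3 stood at 29.8% with the merged list and 21.2% with the stricter threshold. That threshold left 7 WT H3K4me1 peaks, hence the 0 and no kept share. The cause of the other shifts was not tested. Camera has no robust option, count tests did not apply, and comparisons that need gene coordinates were not run. TPM and peak lists keep no depth, so the effect of depth was not tested.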

Other observations

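All tests here were chosen only after the result was seen, except the splits of the libraries for gene lists, the chance and few-genes tests of chromosome 6 and the test of random background calls in the NANOG lists. Imprinted genes, noticed through H19 and Peg10, were among the genes of largest change. Of 15 genes expressed from the maternal allele 11 rose and 2 fell, among them Cdkn1c, a cell cycle inhibitor, from 0.794 ± 0.190 to 21.5 ± 0.860 TPM, Phlda2, a restrainer of placental growth, from 10.5 ± 1.02 to 123 ± 2.72 TPM, and the noncoding RNA Meg3, from 49.9 ± 1.13 to 205 ± 4.16 TPM. Of 14 expressed from the paternal allele, not counting Snurf, which shares a transcript with Snrpn, 9 rose and 3 fell, with Igf2, a fetal growth factor, going from 1.36 ± 0.283 to 19.1 ± 0.292 TPM, Snrpn, a splicing factor, from 59.3 ± 3.12 to 262 ± 2.53 TPM and Plagl1, a zinc finger factor, from 7.26 ± 0.474 down to 0.847 ± 0.0206 TPM. On the members not yet looked at, the hypothesis that imprinted genes rose as a class held in the maternal list (camera p = 0.000202, or p = 0.0170 with an estimated correlation) and in the paternal list (p = 0.00117, or p = 0.0260 with an estimated correlation). Adjusted over the 6 lists tried here, which was added after these values were seen, both passed with the preset correlation (adjusted p = 0.00121 and 0.00351) and neither with an estimated one (adjusted p = 0.0780 for each). These paternal values count Snurf and Snrpn apart, and without Snurf they were p = 0.00443, or p = 0.0395 with an estimated correlation, and after adjustment adjusted p = 0.00886 and 0.118. The maternal values likewise count neighbouring genes apart: Meg3, Rian and Mirg on chromosome 12, and Cdkn1c, Phlda2, Slc22a18, Cd81 and Tssc4 on chromosome 7. The maternal rise thus rests on fewer loci than genes, and no test by locus was run. Each parental class pools genes of different control regions, so a rise of both weighs neither for nor against a loss of methylation there. Methylation and allele-specific reads were not analysed here. Fibroblast markers rose too, in 6 of the 7 cases tested while 13 more stayed below the filter, as did 10 of 16 trophectoderm markers, so a change in the mix of cells was not separated from a rise of the class.

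ERK response genes rose in 12 cases of 19 and fell in 5. Etv4, a transcription factor induced by FGF, went from 1.52 ± 0.320 to 31.6 ± 1.66 TPM and the receptor Epha2 from 13 ± 0.882 to 54.4 ± 1.43 TPM. A rise of FGF and ERK response is a hypothesis that the 10 members not yet looked at left undecided (camera p = 0.00362, but p = 0.0899 with an estimated correlation). A fall of LIF and STAT3 response was not decided by its unseen members (camera p = 0.400, or p = 0.659 with an estimated correlation). DNA methylation genes parted, with Dnmt3b at 4.43 ± 0.398 and 26.4 ± 0.533 TPM and Uhrf1, which guides maintenance methylation, at 205 ± 2.80 and 62.6 ± 0.515 TPM in WT and knockout (camera p = 0.143 on unseen members, or p = 0.200 with an estimated correlation). One-carbon metabolism genes were likewise undecided (camera p = 0.320, or p = 0.372 with an estimated correlation), with 9 falls and 4 rises among all 15 tested. Among the falls, Dmgdh, which acts after Bhmt on dimethylglycine, went from 21.3 ± 0.813 to 0.594 ± 0.0544 TPM. The list also held Upp1, uridine phosphorylase, which is not a one-carbon enzyme and fell from 641 ± 9.70 to 75.1 ± 1.81 TPM.

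NANOG peak numbers fell in knockout replicate 1 and rose in knockout replicate 2. In replicate 1 the shorter list was nested in the longer, with 96.4% of knockout peaks among WT peaks and 1.77% of the weakest and 60.5% of the strongest WT quartile kept, which is consistent with weak peaks missed in the knockout list, and equally with a uniform loss of binding. In replicate 2 weak peaks missed in the WT list cannot be the whole cause, since 31.0% of the WT list lay in the knockout one. Nor did the extra knockout peaks lie at random along the chromosomes, since 68.3% of them met a histone mark, 8.85 times the mean of shifted positions. Of the knockout peaks also in the WT list, 88.2% met one. Shifted positions cannot exclude background calls that gather in marked chromatin. Whether NANOG binding was lower in knockout cells cannot be told apart from depth, because the log2 ratio in replicate 2 was 0.997 and the depth of no list is known.

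Genes of chromosome 6 had a median log2 fold change of -0.37 against -0.19 on other chromosomes, among 550 genes, and the difference was -0.17 with quantile normalization and -0.18 with median-of-ratios scaling. Of 10000 random sets matched on expression, 0 had so low a median, the lowest being -0.30. Chromosome 6 lay furthest from all genes of the chromosomes compared, at -0.166, ahead of chromosome 15 at 0.124. The sets allow neither for picking the most extreme chromosome nor for neighbouring genes that move together, so chance was not excluded. Without 2-fold calls 71.2% of the difference remained, past the limit set in advance against a few strongly changed genes, but with a bootstrap range of 52.0 to 88.0%, added once the value was known, that spans the limit. A difference in copy number of chromosome 6 in part of the cells of either genotype may be a candidate explanation, and stayed undecided at 66.7% of bands (10 of 15) below the median of other chromosomes, with Nanog and Dppa3 on it. Its share of autosomal peaks in WT and knockout was 12.4 and 12.3% for NANOG of replicate 1 and 8.51 and 6.94% for replicate 2. For H3K4me1 it was 8.18 and 7.32%, for H3K27ac 5.60 and 5.72%, and for H3K4me3 4.05 and 3.71%. These shares also depend on peak calling and were not tested as a measure of copy number.

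Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls as the real split. It gave 10127 genes (3446 higher, 6681 lower) and 10 lists, and the highest of the other splits gave 0 genes in each of these counts and 7 lists. Every other split puts both genotypes in each group, in unequal numbers. Part of the genotype difference therefore stays in its contrast, and the rest widens the spread within groups. The counts of the other splits are thus no null for gene or list calls.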
